A study of Mus musculus with 231 samples.

How the data were processed

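RNA was measured in 231 whole-brain samples (cerebellum removed) from ENU-mutagenized mice. Per the labels' protocols, tissue was kept in a stabilising solution for up to 5 days, total RNA was extracted on a 96-well system, and 4 ng per sample was converted to cDNA with a kit that captures the 3' ends of transcripts and amplified for 8 cycles. An in-line index marked each sample of a row, and the 12 cDNAs of a row were combined. Each of the 96 pools made from 12 plates entered a tagmentation-based library preparation with 400 pg, and the pools were combined into a library of 1152 samples. Such 3' libraries give reads near the transcript end, so they do not measure whole transcripts.

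The submitters' processing notes name the aligner GSNAP and the mouse genome build GRCm38; its version, the read counter and the annotation are not given in the sources used here. Per the design text, expression values are held in a companion series, and they were not used here. The deposited file analysed is a lookup table with 3 columns, which are a row number, a library name and the label of a part of the processed data. Its only numeric column numbers the rows, and 0 columns hold a measurement. No unit of expression, normalisation or depth therefore applies, and no count test, fold change or confidence interval was computed. The reference annotation was not used.

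Library names were split into the line, the mouse number, the well, the plate label (neuro and a number) and the number after S, which is constant within a row of a plate label and is treated here as the pool. The line is the text before the strain abbreviation, and the mouse number is the digits that follow the generation number 3 in the name; this reading comes from the names and the protocol. Libraries were grouped by line and matched to the lookup table by the whole name. The 23000 names in the table outside the series were used to count the libraries assigned to each part, those that share a line name, plate label or pool with the series, and those in the run of consecutive plate labels around it. Counting was done in Python 3.11.15 with pandas 2.3.3. The counts of matched libraries, of libraries per line, plate label and pool, and of libraries per part, with the matching alternatives, were fixed before the lookup table was examined but after the library names had been read. The order of mouse numbers along a row and the counts of names that share a line name, plate label or pool with the series or lie in the run of plate labels were chosen afterwards. The planned comparison of numeric values per library between lines was not carried out because the table has no such column, and the marker gene lists planned for microglia, astrocytes, oligodendrocytes, endothelium, choroid plexus, T cells, blood, and the interferon response were not used. Under the rule set for named genes, no gene was named.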

Results

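The data collected were brain transcriptome libraries from mice carrying mutations induced with ENU (N-ethyl-N-nitrosourea), an alkylating mutagen that introduces point mutations at scattered sites in the genome. Per the labels, C57BL/6NCrl founder males received 3 treatments of 100 mg/kg. Their descendants were bred to generation 3, so that induced mutations could occur in the homozygous state in some animals. Brains without the cerebellum were taken, usually at 8 to 12 weeks of age. The cohort was screened for animals with abnormal inflammatory states in the brain, with exome sequencing used to look for candidate variants. Expression values, read depths and genotypes were not analysed here. The file used pairs library names with parts of a larger processed data set, so the measurements below are counts of libraries, and no gene is named.

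The series held 231 libraries, each carrying its own mouse name. They belonged to 20 lines, a line being the set of libraries that share the first number in the library name, and the protocol states that about 12 siblings were usually screened per pedigree. Of the 20 lines, 18 had 12 libraries each. Line ENU58496 had 9 libraries and line ENU58513 had 6. All 231 libraries shared the same organ label and the same value in the remaining annotation field. The labels gave no treated, mutant or control group within a line, so no comparison of affected with unaffected animals was defined, and no affected animal was inferred from the names.

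The design implies a comparison of each animal with its siblings within a line, and a comparison between lines. How far either can be separated from library preparation depends on the plate layout. Per the protocol, the libraries of 1 row of a plate were pooled after cDNA amplification and carried through the second library preparation together. Each of the 20 lines lay in 1 row of 1 plate label and in 1 pool, and 0 lines were split over several pools. Siblings within a line therefore shared their plate label and pool, so a comparison among them is not confounded with either. Conversely, 0 of the 20 pools held more than 1 line of this series. Among these libraries a difference between lines cannot be told apart from a difference between pools.

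The lines were spread over 7 plate labels. Labels neuro2232 and neuro2237 carried 48 libraries each, from 4 lines apiece. Label neuro2231 carried 45 libraries from 4 lines, neuro2238 carried 36 from 3 lines, and neuro2233 carried 30 from 3 lines. Labels neuro2236 and neuro2239 carried 12 libraries and 1 line each, ENU58503 and ENU59085 respectively. The other 18 lines shared their plate label with at least 1 further line, so a comparison of lines within a plate label is possible for those 18 lines, although each would still differ in pool. For ENU58503 and ENU59085, line and plate label coincide within the series.

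Within a row, the number that ends the mouse name rose steadily with the well column in 10 of the 20 lines and did not in the other 10. In the first 10 lines, including ENU58499 and ENU5934, the order of wells and the numbering of the siblings cannot be separated. The count required every step to rise, so a single animal out of order, as in ENU58500, placed a line among the other 10. In all 20 lines each animal had a single library in a single well. A difference between single siblings therefore cannot be told apart from a difference between wells in any line.

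All 231 library names were found, each once, in the lookup table, which lists 23231 distinct library names. The table assigns them to 3 parts, which hold 7743, 7743 and 7745 libraries. Every library of the series was assigned to part 3 of the processed data, so within the series none of the 20 lines is divided between parts.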

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

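The number of libraries found in the lookup table was 231 with the whole name matched, and 231 under each of the 3 alternatives, which were matching the name only up to the well and plate label, ignoring case and blanks, and counting each distinct name once. The whole name already matched every library and every listed name is distinct, so the last 2 alternatives had no room to change the count and say nothing about its stability. Matching the shortened name counts the listed names that match, so it was able to give a higher number. A comparison without the lines of fewer than 12 libraries was not run, because it applied to numeric values per library, of which the table holds 0 columns. Leaving out single animals was not applied, since no mean or test was computed. No paired analysis was possible because no result comes from a test. Sequencing depth limits none of these counts.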

Other observations

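The following counts were chosen after the table had been seen. The difference between pool number and plate row was taken from the series' own libraries, and the other counts use names outside the series. In each of the 7 plate labels, the number after S minus the rank of the plate row was a single value. That value was a multiple of 8 and ranged from 24 for neuro2231 to 88 for neuro2239. Labels neuro2236 and neuro2239 each held 1 row of the series, so a single value was fixed there in advance. The 12 consecutive plate labels from neuro2228 to neuro2239 list 1152 libraries, with 96 in each label, pool numbers from 1 to 96 and 12 libraries in each of the 96 pools. The start of this run was set by counting back from neuro2231 in steps of 8. Its end is the highest plate label of the series. The length of 12 labels and the pool range therefore largely follow from that choice. The 96 libraries in each label were free to differ, and they equal the number that the protocol states. The 12 libraries in each pool also equal the protocol's number. If each label is a full plate with 1 pool per row, the 12 follow from the 96 and are not a separate match. The series holds 20.1% of those 1152 libraries.

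The table also lists 9 libraries outside the series that lie in pools of this series. Of these, 3 carry the name of line ENU58496, which raises that line from 9 to 12 libraries in its pool. The other 6 fill the pool of line ENU58513 and belong to another line, so 19 of the 20 pools list 1 line and 1 pool lists 2. That pool is the only one of the 20 that lists libraries of different lines, with 6 libraries on each side. None of these 9 libraries was analysed here.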
